A study of Homo sapiens with 12 samples.

How the data were processed

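The samples were K562 cells, an established human chronic myeloid leukemia line, edited by homology-directed repair so that MYC carried either a control 3' UTR or the 3' UTR of HPRT1. Per the labels, cells were treated for 6 hours with DMSO, with actinomycin D at 1 µg/mL or with AZ-5576 at 1 µM, with 2 samples for each genotype and treatment and 12 samples in all. Total RNA was measured by directional sequencing after depletion of ribosomal RNA, and Drosophila S2 material was added to the RNA as a spike-in. Actinomycin D is a DNA-binding inhibitor of transcription, and AZ-5576 is an inhibitor of CDK9, the kinase that releases paused RNA polymerase II.

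Per the file headers, the authors counted fragments with featureCounts (Subread 2.0.0), with the strand setting 2 for reversely stranded libraries. The options chosen also counted a fragment that aligned to several places, or overlapped several features, at each of them. The exon table used a joint annotation of the human genome GRCh38 and the Drosophila genome BDGP6, both from Ensembl 90, with an added row for the edited MYC locus. The intron table used a list of intervals per human transcript. Per the submitters' processing notes, reads were trimmed with cutadapt 2.1 and aligned with HISAT2 2.1.0. The deposited counts are raw fragment counts, with 16 columns of sample values in each of the 2 tables.

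None of the 16 columns enters the results given here. The names of 12 of them give a clone code, a treatment and a replicate number, while the labels give the 3' UTR genotype, the treatment and the replicate number, and no clone code. Each of these columns therefore fits 2 samples that differ in genotype. The order of columns and the counts themselves were not taken as a guide to the genotype. The other 4 columns are named for JQ1, a treatment that none of the 12 samples has. No comparison between groups is therefore reported, and depth per sample, spike-in levels, fold changes and tests are not given here. The tests, the rule for named genes, 109 alternatives and 21 gene lists had been fixed before the data were examined. Before these columns were excluded, differential expression fits by treatment and clone code and gene list tests had been run on the 12 columns, and the counts of MYC and HPRT1 had been looked at. Those results were set aside and none of them is given here.

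What was analysed is the set of features that the counts refer to, from the columns of identifiers, coordinates, strand and length (in bases), with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. Coordinates are 1-based and are those of the deposited tables on GRCh38. Transcripts were assigned to genes, and genes to biotypes, with GENCODE 29, which corresponds to Ensembl 94 on the same assembly. Of the 58302 human gene identifiers, 58039 were found there and 263 were not, and 41836 had a symbol in the table of gene names. Of the 219870 intron rows, 179910 belonged to a transcript whose gene had a row in the exon table, and the other 39960 were left out. Of those, 38898 had a transcript identifier that was not found in GENCODE 29, of which 21136 lay on sequences that also carry human genes of the exon table and 17762 on other sequences. A further 31 had an identifier found there but lay on other sequences, and 1031 belonged to a gene without a row in the exon table. An intron row was called exon-free when none of its bases beyond the first base of each interval lay in an exon of any human gene on its strand. Genes were called overlapping when their exons shared at least 1 base with an exon of another human gene on the same strand. These definitions, and the genes named as examples of a list, were chosen after the tables had been seen. The overlap search was checked against a comparison of every pair of exons on 1 strand of chromosome 21.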

Results

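The series was designed to ask how RNA decay shapes the response of leukemia cells to drugs that disturb transcription, with MYC given either a control 3' UTR or that of HPRT1 in K562 cells. Total RNA was sequenced from 12 samples in 6 groups of 2, made of 2 genotypes and 3 treatments. The genotypes were not compared, because the names of the count columns give clone codes and the labels give 3' UTR genotypes. The counts were not used to decide which clone code has which genotype. A comparison of treatments within a clone code can be made from the column names, and it was left out by choice. The account below covers the features that were counted, and which genes and gene groups can be read in the exon and intron tables.

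The exon table held 75862 rows, of which 58302 were human genes, 17559 were Drosophila genes and 1 was the edited MYC locus. MYC (ENSG00000136997), a transcription factor that drives growth and proliferation, lay on chromosome 8 from 127735434 to 127741434 on the plus strand of GRCh38, with 3 merged exons and 3001 bases of exon sequence. HPRT1 (ENSG00000165704), an enzyme of purine salvage, lay on chromosome X from 134460153 to 134520513, with 11 merged exons and 1624 bases. PVT1 (ENSG00000249859), a long noncoding RNA gene downstream of MYC, lay on chromosome 8 from 127794533 to 128101253, with 21 merged exons and 5493 bases. The edited locus lay on a contig of its own, MUTlocus, as a row of 2271 bases without introns. The row was named for MYC, a GSG linker, the P2A peptide and GFP. Its name gives neither 3' UTR, and whether the row separates the genotypes was not examined. Fragments from sequence that the contig shared with MYC were eligible to be counted in both rows, since the authors' counting kept fragments aligned to several places. A transcript of MYC that carries the 3' UTR of HPRT1 has sequence in common with the HPRT1 row, so fragments from that sequence were eligible for the HPRT1 row. Whether the MYC row holds 3' UTR sequence that such a transcript lacks was not examined. The exons of MYC and HPRT1 overlapped no exon of another gene on their strand, and those of PVT1 did.

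Exons of 5725 human genes, 9.82% of the total, overlapped an exon of another gene on the same strand. Among protein-coding genes the share was 15.84% (3139 of 19817). A fragment in such a stretch was counted for each gene. The host genes of small nucleolar RNAs were the list with the largest share of overlapping members, 12 of 15. How much of each gene's exon sequence was shared was not measured. Of the cytosolic ribosomal protein genes 35 of 79 overlapped another gene, as did 10 of 28 MYC targets, 5 of 8 nuclear long noncoding RNAs and 5 of 13 mitochondrially encoded mRNAs. In contrast, no overlap was found for the 18 replication-dependent histone genes matched to the table or the 13 genes of NF-kB and inflammatory signalling.

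The intron table held 219870 transcript rows and no Drosophila rows, so that the spike-in can be read from the exon table alone. Of the 1048399 intron intervals matched to genes, 1042794 (99.47%) started on the last base of an annotated exon, and 3879 started on the base after one. At the other end, 1042664 intervals (99.45%) stopped on the base before an annotated exon. The 1042794 intervals of the first kind took in 1 exon base at their lower coordinate. Intervals and exons were matched by position, without regard to gene or strand. Where the exon is of the same gene, it is the upstream exon on the plus strand and the downstream exon on the minus strand. With fragments counted for every feature they overlapped, a spliced fragment covering such a base on the strand of the interval met the overlap needed to be counted as intronic.

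Intron rows also held exons of other transcripts. Of the 179910 matched rows, 35321 (19.63%) were free of annotated exons beyond the starting base and 144589 were not. In the rows that held exon sequence, its median share was 5.71% of the length. An exon-free row existed for 27392 of the 35383 genes with any matched intron row, and for 13739 of 18811 such protein-coding genes (73.04%). Rows left out as unmatched may belong to some of the same genes. The numbers of intron rows per gene and per gene group, here and below, therefore cover matched rows only. The first base of each interval, which the deposited counts include, was left out of this definition and of the tallies of gene groups below, and with it included only 129 genes had such a row. MYC had 7 intron rows, of which 3 were exon-free, the longest with 3002 bases. HPRT1 had 3 rows and 1 exon-free row of 37574 bases. PVT1 had 20 rows, of which 1 was exon-free, with 76737 bases against 302979 in its longest row.

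Among the matched rows, gene groups differed in whether they had an intron row, and in whether any such row was exon-free. The 13 mitochondrially encoded mRNAs had no intron row. Of the 13 RNA polymerase III transcripts listed, 12 were matched to the exon table by symbol, and these had no intron row either. Of the 19 replication-dependent histone genes listed, 18 were matched, and 13 of the 18 had no intron row. Among the 29 immediate-early and AU-rich short-lived mRNAs, 25 had an intron row and 19 an exon-free one. JUN, JUNB, IER5 and RHOB had no intron row, whereas FOS and EGR1, transcription factors induced by growth signals, had exon-free rows. Every interferon response gene listed (15 of 15) had an exon-free row, as did 24 of 26 mitosis and cell cycle genes, 19 of 23 mRNA decay factors, 18 of 22 erythroid genes and 17 of 19 P-TEFb and pausing factors. The figure was 18 of 28 for MYC targets, 12 of 16 for the BCL2 family and 16 of 20 for p53 targets. It fell to 26 of 79 for cytosolic ribosomal proteins and 5 of 15 for small nucleolar RNA host genes. Every member of both of these lists had an intron row.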

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

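The counts of genes below, their definitions and the other definitions tried were chosen after the tables had been seen. The number of genes with an exon-free intron row was 27392. It was 22759 when exons of both strands were counted against a row and 30393 when only exons of protein-coding genes were. With the first base of each interval included, it came to 129, because nearly every interval starts on an exon base. The number of genes whose exons overlap another gene was 5725 on the same strand, 5313 with an overlap of at least 50 bases, and 16279 without regard to strand, a number that bears on counting without strand and not on the strand setting used. None of the 109 alternatives fixed earlier for the comparisons between groups (scaling, test, filter, replicate block and left-out libraries) was run. For the labelled groups of 3' UTR genotype and treatment, no paired analysis was possible because each count column fits 2 labelled samples that differ in genotype. For treatments within a clone code, a paired fit can be made from the column names, and it was left out by choice. Of the intron rows, 39960 were left out as unmatched, and the cause was not tested. Some of them may belong to the genes counted above, and none of the definitions tried took them in.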

Other observations

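The remaining gene lists fixed before the data were examined were covered as follows. As above, exon-free leaves out the first base of each interval, which the deposited counts include, and only matched intron rows were considered. An exon-free intron row was present for 4 of 4 genes of a list made of MYC, HPRT1, PVT1 and CASC11, 10 of 12 megakaryocytic genes, 9 of 15 markers of other cell types, 11 of 17 genes of the integrated stress and unfolded protein response, 8 of 13 glycolytic genes, 10 of 13 genes of NF-kB and inflammatory signalling and 3 of 8 nuclear long noncoding RNAs. In 2 lists, 1 member each was not matched to the exon table by symbol, H3C2 among the histones and RNY5 among the RNA polymerase III transcripts. All members of the other 19 lists were matched. The lists name genes of interest for this design and were not chosen on these samples.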
